A study of Homo sapiens with 12 samples.

How the data were processed

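Gene expression was measured on 12 oligonucleotide arrays of 1 type, each with 54675 probe sets, from 293T cells, a human embryonic kidney line. The cells had been transfected with polyethylenimine and collected 48 hours later, and 12 micrograms of total RNA per sample had been labelled with biotin. The labels give 3 groups of 4 biological replicates, which are an empty vector, a vector with the tRNA gene chr1.tRNA68-Gly(GCC), and a vector with a hairpin for CU1276, the small RNA that the labels describe as coming from that tRNA.

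The deposited values are MAS5 signal intensities on a linear scale, 1 column per array. The submitters' processing notes name MAS5 and give no version. The 2% trimmed mean of each deposited column was 500.1, so the authors had scaled each array to a common intensity. Neither a genome build nor an annotation version is given in the sources used here, so no coordinates are printed. Gene symbols came from the annotation of the array with names brought up to date by Entrez identifier against a RefSeq table, which changed 0 symbols and lacked 54. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed with a gene. Counted among these were 62 controls.

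Signals were taken to log2 with no offset. Control probe sets were left out, as were 21845 dim ones with a mean log2 signal under the 40th percentile, a geometric mean signal of 43.3. This left 32768 tested probe sets, 26675 of them with 1 symbol, for 13952 genes. A gene was represented by its brightest probe set with 1 symbol. Probe sets with several symbols were tested and counted but not named, with 1 exception given in the results.

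A model with 3 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). P values were adjusted by Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05, two-sided. Each vector was compared with the empty vector, and the hairpin vector with the tRNA vector. Beside it, a plain two-sample test per probe set was run. Single values were compared by exact permutation of the 8 arrays of a comparison, two-sided, for which the smallest possible p is 0.0286. Fold changes are hairpin or tRNA vector over the reference group, on the log2 scale unless a fold is named, and ± after a log2 fold change is its limma standard error with n = 4 arrays per group.

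Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over 34 lists, and again with a correlation estimated per list. The function fry was run beside it and tests whether the genes of a list move, on balance, 1 way; 0 lists passed it in each of the 3 comparisons (smallest fry adjusted p = 0.129, 0.969 and 0.0994), and 3, 0 and 2 with the batch as a block. These were p53 targets, DNA replication and TGF-beta, matrix and adhesion with the tRNA vector, and p53 targets and DNA replication between the vectors. The lists, 1066 symbols of which 860 were measured, were the RPA complex, DNA replication, DNA damage signalling, homologous recombination and Fanconi anaemia, excision and mismatch repair, end joining, p53 targets, E2F and G1/S genes, G2/M and mitosis, histone genes, microRNA machinery, tRNA transcription and processing, aminoacyl-tRNA synthetases, serine, glycine and one-carbon metabolism, the integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early genes, sterol and fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, splicing factors, apoptosis regulators, metallothioneins and oxidative stress, TGF-beta, matrix and adhesion, and markers of B cells, of T cells and myeloid cells, of fibroblasts, of epithelia and of erythroid cells. A list needed at least 3 measured genes.

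Named genes followed a rule. RPA1, RPA2 and RPA3 were named in each comparison. Where no probe set passed, the 5 highest and 5 lowest by moderated t were named, as values only. Of each list past its threshold the 4 members with the smallest p in the direction of the list were named, and of the lists of DNA damage signalling, p53 targets and DNA replication the 2 with the smallest p. The groups, comparisons, tests, lists, the rule for named genes and the alternatives first listed were fixed before the data were examined.

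24 probe sets for Bacillus control RNAs, which are added to samples in labelling, fell into 3 levels across the arrays. These were read as labelling batches after the data had been examined (arrays numbered 1, those numbered 2, and those numbered 3 and 4). The levels follow the replicate numbers, so labelling cannot be told apart from other differences between replicates. Each batch holds the 3 groups in equal numbers. Values within batches use the same arrays as same-number comparisons, so they are no separate support. For 4 same-number comparisons the smallest possible exact sign-flip p is 0.125. A fit with the batch as a block was added, as was a fit without the 3 arrays of the strongest control signal. Same-number arrays of different groups correlated at r = 0.0987 to 0.356 after removal of group means, above 0.1 in 11 of 12 pairs and not in all. Such pairs had r of 0.0930 or more within a batch and of 0.0203 or less between batches. The labels state no pairing, so the planned fit used no block. Its spread therefore includes that between batches, with a median limma standard error of 0.225 against 0.181 with the batch as a block.

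The alternatives listed first were an offset of 16, no filter, a filter at the 60th percentile (signal 143.5), quantile normalization, centring on the median, no intensity trend, array weights, only the compared arrays, a replicate block, each array left out in turn, an adjusted p under 0.1, a fold of at least 1.5, 1 probe set per gene, and the mean of a gene's probe sets. Overlap between the vectors, which share the empty vector arrays, was set against 100 simulations of groups without change, with the spread of the planned fit and, added later, of the fit with the batch as a block, and against the 6 ways of giving each vector 2 of the empty vector arrays. The methods were tested on simulated data with the spread of these arrays. Of 100 probe sets shifted by 0.5 on the log2 scale, 13, 7 and 6 were recovered in the tRNA vector, hairpin vector and between-vector comparisons, and of 100 shifted by 1, 46, 27 and 36. For arrays, precision is limited by their number, 4 per group, and by signal over background, and there is no depth per sample.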

Results

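The data are signals of 54675 probe sets on 12 arrays, 1 per RNA sample, from 293T cells. There were 4 arrays for the empty vector, 4 for the tRNA vector and 4 for the hairpin vector. The median signal of an array was 75.9 to 104, and log2 signals of any pair of arrays correlated at r = 0.925 to 0.959 across probe sets, which are not independent replicates. Bacillus control RNAs had a mean signal of 1109 to 1197 in the arrays numbered 1, of 216 to 259.7 in those numbered 2, and of 12.3 to 18.4 in those numbered 3 and 4. These 3 levels, read as labelling batches, hold the 3 groups equally. The lowest level lies under the filter signal of 43.3, so the control RNAs alone are weak ground for joining numbers 3 and 4. The ratio of 3' to 5' GAPDH signal, a measure of RNA integrity, was 1.34 ± 0.124 with the empty vector, 1.36 ± 0.129 with the tRNA vector and 1.35 ± 0.223 with the hairpin vector (SD, n = 4), with exact permutation p of 0.8 to 1.

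RPA1, the large subunit of the RPA complex that binds single-stranded DNA in replication and repair, is the transcript the study is known to link to CU1276. The comparison asks whether its level differed with either source of CU1276. The signal of its brightest probe set was 5861 ± 319.6 with the empty vector, 5061 ± 335 with the tRNA vector and 5032 ± 461 with the hairpin vector (SD, n = 4). The log2 fold change against the empty vector was -0.21 ± 0.082 for the tRNA vector, a fold of 0.863, and -0.22 ± 0.082 for the hairpin vector, a fold of 0.857. All 4 tRNA vector arrays (4662 to 5452) lay below all 4 empty vector arrays (5587 to 6297), while the hairpin vector arrays (4587 to 5679) overlapped them. Within the 3 batches the log2 fold change was -0.28, -0.28 and -0.14 with the tRNA vector and -0.15, -0.30 and -0.22 with the hairpin vector. The exact permutation p was 0.0286 for the tRNA vector, the smallest possible, and 0.0857 for the hairpin vector, or 0.0857 and 0.129 after adjustment over the 3 comparisons of RPA1. Both vectors were compared with the same empty vector arrays, so these results are not independent of each other. With each vector the signal of this probe set was lower in 4 of 4 same-number comparisons (smallest possible exact sign-flip p = 0.125). Its unadjusted limma p was 0.0204 for the tRNA vector and 0.0160 for the hairpin vector. With the batch as a block, added after the data were seen, it was 0.00258 and 0.00181. After adjustment over all tested probe sets, the limma adjusted p was 1 and 0.9999, and 0.406 and 0.808 with the batch as a block. In the RPA complex, adjusted over the list alone, RPA1 passed with the hairpin vector (limma adjusted p = 0.0479) and not with the tRNA vector, against 0 genes of that list over all genes in each comparison.

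The next brightest RPA1 probe set differed from it. Its signal was 4326 ± 750 with the empty vector, 4463 ± 594 with the tRNA vector and 3756 ± 400.2 with the hairpin vector (SD, n = 4), with log2 fold changes against the empty vector of 0.053 ± 0.13 and -0.19 ± 0.13. The remaining, dim one gave 0.094 ± 0.25 and 0 ± 0.25. Between the vectors the brightest RPA1 probe set differed by -0.010 ± 0.082 (limma adjusted p = 0.9997), a sign that turned with quantile normalization and without single arrays. The next brightest differed by -0.245 ± 0.13 and was lower in 4 of 4 same-number comparisons (exact permutation p = 0.114). Its limma adjusted p was 0.9997, and 0.401 with the batch as a block. The dim one differed by -0.094 ± 0.25. RPA2 and RPA3, the other subunits, had log2 fold changes of -0.012 ± 0.081 and -0.027 ± 0.089 with the tRNA vector, -0.021 ± 0.081 and -0.052 ± 0.089 with the hairpin vector, and -0.0090 ± 0.081 and -0.026 ± 0.089 between the vectors, and each of these signs turned under at least 1 alternative. As a list the RPA complex did not pass in any comparison (camera adjusted p = 0.512, 0.301 and 0.982).

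**Figure D1:**
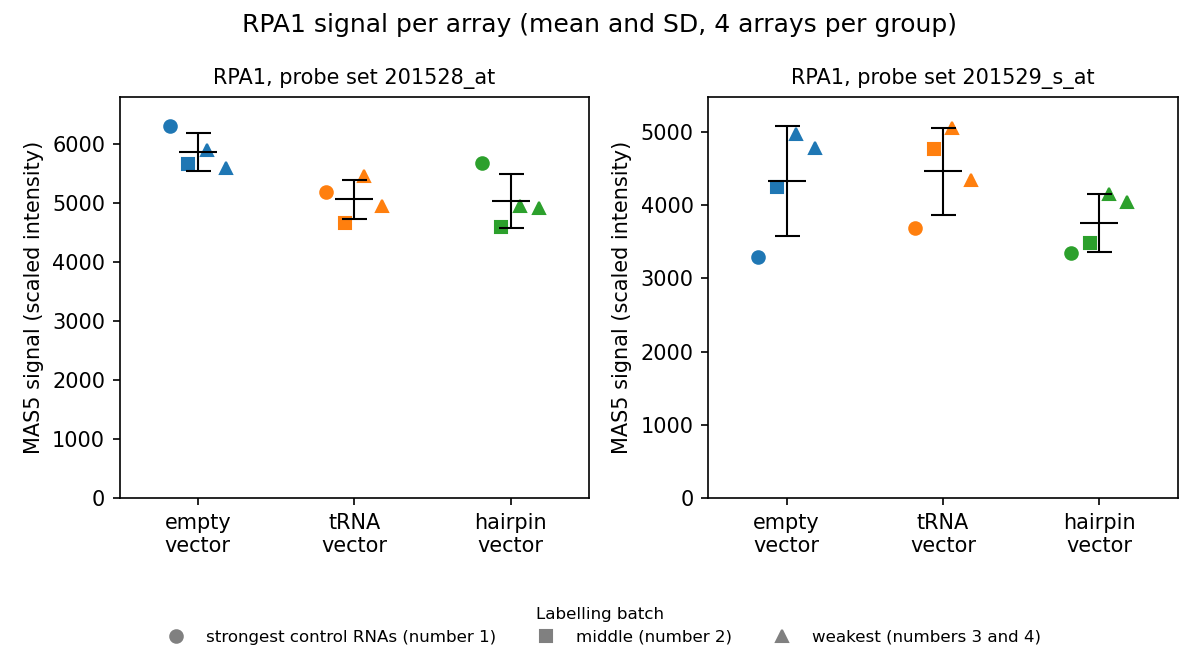
Signal (linear, vertical axis) of the brighter RPA1 probe sets on each array, with the mean and SD of the 4 arrays per group and marker shapes for the 3 labelling batches. On the brightest (left) the group means were 5861, 5061 and 5032, and on the other (right) 4326, 4463 and 3756.

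With the tRNA vector, 20 of 27 measured p53 target genes had a lower mean than with the empty vector. The list mean stood at -0.11 on the log2 scale, with an SD of 0.040 and 0.070 over the 4 arrays of the groups. The list passed camera with the preset correlation (adjusted p = 7.07e-05) and not with an estimated correlation (adjusted p = 0.248). Its exact permutation p was 0.0857. The members with the smallest p in that direction were SPATA18, which takes part in mitochondrial quality control, at -0.60 ± 0.15, TP53I3, a quinone oxidoreductase, at -0.45 ± 0.12, ZMAT3, an RNA-binding protein, at -0.34 ± 0.12, and AEN, an exonuclease of apoptosis, at -0.25 ± 0.082. Transcripts of ribosomal proteins were higher in 45 of 48 and those of oxidative phosphorylation in 36 of 47, by means of 0.094 and 0.070. These too passed camera with the preset correlation and not with an estimated correlation (adjusted p = 0.898 for both). The comparison asks which transcripts differ when the tRNA gene is added.

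The p53 target mean was lower in 4 of 4 same-number comparisons, for which the smallest possible exact sign-flip p is 0.125. Batch values, which come from the same arrays, were -0.13, -0.065 and -0.12. The list did not pass fry (adjusted p = 0.129). Its median moved from -0.10 to -0.16 without empty vector array 2. With the batch as a block, an alternative added after the data were seen, the camera adjusted p was 1.95e-05, or 0.0321 with an estimated correlation, and the fry adjusted p was 0.00334. Adjusted over the list alone 2 of its genes passed in limma (SPATA18 and TP53I3, adjusted p = 0.0218), against 0 over all genes. For ribosomal proteins the camera adjusted p was 2.93e-06, with adjusted p = 0.898 with an estimated correlation and an exact permutation p of 0.371, and the sign was not kept within batches (-0.17, 0.31 and 0.12); that call ended without tRNA vector array 2 (camera adjusted p = 0.390) and with quantile normalization (0.655). The median, 0.10, was 0.0073 with quantile normalization and ran from 0.011 (without tRNA vector array 2) to 0.167 (without tRNA vector array 1) when single arrays were left out. For oxidative phosphorylation the adjusted p was 6.53e-04, or 0.898 with an estimated correlation, and batch values were -0.044, 0.088 and 0.12; that call ended without empty vector array 2 (camera adjusted p = 0.0575) and with quantile normalization (0.380), and over all settings its median, 0.063, ran from 0.027 to 0.12. In limma 0 genes of either list passed adjusted over the list alone, and 0 over all genes. The members with the smallest p were RPS9 (0.17 ± 0.063), RPS21 (0.21 ± 0.10), RPL23A (0.18 ± 0.094) and RPL36 (0.12 ± 0.067) among ribosomal proteins, and NDUFV1 (0.37 ± 0.12) and NDUFA1 (0.20 ± 0.087) of respiratory complex I, UQCRC1 of complex III (0.18 ± 0.075) and COX7C of complex IV (0.16 ± 0.076).

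No single transcript passed the test. limma gave 0 changed probe sets after adjustment (smallest adjusted p = 1), with 1238 at an unadjusted p under 0.05 (559 higher, 679 lower) where chance gives 1638, and the plain two-sample test also gave 0. The unadjusted count was 2524 (1213 higher, 1311 lower) with the batch as a block, against the same 1638. Probe sets are not independent and no range around that number was computed, so no excess over chance is claimed. Values only, the lowest by moderated t were RAB13, a GTPase of vesicle transport (-0.60 ± 0.11), CAMSAP2, which binds microtubule minus ends (-0.46 ± 0.096), CIRBP, a cold-inducible RNA-binding protein (-0.40 ± 0.081), DCTN4, a dynactin subunit (-0.40 ± 0.078), and LRRC58 (-0.40 ± 0.081). The highest by moderated t were DTX2, a ubiquitin ligase of the Notch pathway (2.70 ± 0.53, from a dim 21.4 ± 6.44 to 142 ± 49.7), GHET1, a long noncoding RNA (1.09 ± 0.26, with signals of 80.0 ± 9.49 and 169 ± 9.45), TSPAN31 (0.62 ± 0.14), TBL1X, part of a corepressor complex (0.43 ± 0.094), and CUTA (0.29 ± 0.070). Other probe sets did not all share the direction for CIRBP (1 of 4 did), DCTN4 (1 of 2), TBL1X (2 of 4), ZMAT3 (2 of 4), RPS21 and RPL36 (0 of 1 each). With the replicate block, an alternative fixed at the start, limma called 0 (smallest adjusted p = 0.0842). With the batch as a block, chosen after the data were seen, limma called 4 probe sets after adjustment, all lower. They were CUL4B, a scaffold of ubiquitin ligases (-0.63), BEX1 (-0.61), ZNF654 (-0.59) and a probe set not listed with a gene (-0.63), at an adjusted p of 0.0489 each, with the same sign in all 3 batches. That fit favours a difference that holds across batches, so the shared sign adds no support. These 4 were chosen after their values were seen.

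Genes of the DNA damage response and replication gave no list call by camera with the tRNA vector. Of 33 DNA damage signalling genes 17 were lower (mean -0.019, camera adjusted p = 0.648), among them ATM, the kinase that responds to double-strand breaks (-0.36 ± 0.14), and MRE11, a nuclease of break repair (-0.20 ± 0.11, a direction that 0 of 2 other probe sets shared). Of 46 DNA replication genes 33 were higher (mean 0.036, camera adjusted p = 0.301), with POLD2 (0.17 ± 0.11) and POLE2 (0.13 ± 0.076), subunits of replicative polymerases, at the smallest p. The replication list passed fry with the batch as a block (fry adjusted p = 0.0397) and not in the planned fit (0.882), nor camera with that block (adjusted p = 0.190). Its exact permutation p was 0.4. Means were -0.027 for homologous recombination and Fanconi anaemia genes, 0.0018 for excision and mismatch repair, where the median was -0.027 and the test pointed down, -0.0079 for end joining, where the median was 0.0065, -0.035 for E2F and G1/S genes, where the median was 0.00013, and -0.0090 for G2/M and mitosis genes. The E2F and G1/S mean was lower in 4 of 4 same-number comparisons (exact permutation p = 0.0286, the smallest possible). The camera adjusted p of these 5 lists were 0.648, 0.914, 0.933, 0.648 and 0.875, and 0 genes of these 7 lists passed adjusted over the list alone. MicroRNA machinery (mean -0.019), tRNA transcription and processing (0.027), histone genes (0.042) and aminoacyl-tRNA synthetases (0.00086, where the test pointed down) did not pass either (camera adjusted p = 0.861, 0.563, 0.972 and 0.914).

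With the hairpin vector, 14 of 18 measured genes of the aminoacyl-tRNA synthetase list had a lower mean than with the empty vector. It holds enzymes that charge tRNAs and a scaffold of their complex. The list mean stood at -0.055 on the log2 scale. The list passed camera with the preset correlation (adjusted p = 0.0281) and not with an estimated correlation (adjusted p = 0.836). Its exact permutation p was 0.229, and it passed in 14 of 23 other settings. AARS1, which charges alanine tRNA, stood at -0.25 ± 0.066, CARS1, for cysteine, at -0.28 ± 0.075, WARS1, for tryptophan, at -0.20 ± 0.12, and AIMP1, a scaffold of the synthetase complex, at -0.15 ± 0.072. Separately, the brighter probe sets annotated to both DGCR8, the partner of DROSHA in microRNA processing, and MIR1306, the microRNA within that gene, had 1.49 to 1.60 times the signal of the empty vector. The comparison asks which transcripts differ when CU1276 is supplied as a hairpin.

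Within batches the mean of the synthetase list was -0.097, -0.066 and -0.028, and with the batch as a block the camera adjusted p was 0.00881, or 0.857 with an estimated correlation. It did not pass fry (adjusted p = 0.969, and 0.343 with that block). The call ended with several alternatives, among them quantile normalization, no filter, and each fit without empty vector array 1, empty vector array 2 or hairpin vector array 4 (0 lists each). Without the 3 arrays of the strongest batch its camera adjusted p was 0.2685, and ribosomal proteins passed in its place as higher (median 0.076, camera adjusted p = 9.90e-04). These fits used the preset correlation. In the planned fit the estimated correlation of the ribosomal list was 0.70, with a camera adjusted p of 0.922. There were 2 lists, the synthetases and ribosomal proteins, without empty vector array 4, hairpin vector array 1 or hairpin vector array 2. The synthetase median, -0.048, ran from -0.0995 (without hairpin vector array 1) to -0.022 (without empty vector array 1). Adjusted over the list alone, 2 of its genes passed in limma (AARS1 and CARS1, adjusted p = 0.0219), against 0 over all genes. For WARS1 the other probe set had the opposite direction.

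Over all probe sets limma gave 0 changed after adjustment (smallest adjusted p = 0.336), with 867 at an unadjusted p under 0.05 (468 higher, 399 lower) where chance gives 1638, and the plain two-sample test gave 0. The unadjusted count was 1803 (972 higher, 831 lower) with the batch as a block, against the same 1638. Probe sets are not independent and no range around that number was computed, so no excess over chance is claimed. Values only, the lowest by moderated t were MAP2K4, a kinase that activates JNK (-0.49 ± 0.086), MANF, a secreted protein induced by endoplasmic reticulum stress (-0.32 ± 0.067), RC3H2, which promotes mRNA decay (-0.79 ± 0.17), CDH22, a cadherin (-1.10 ± 0.25), and STK24, a protein kinase (-0.30 ± 0.074). The highest by moderated t were DNAJC11, a mitochondrial cochaperone (0.39 ± 0.088), CHPF2, an enzyme of chondroitin synthesis (0.52 ± 0.12), COPE, a coatomer subunit (0.67 ± 0.17), PFAS, of purine synthesis (0.49 ± 0.13), and TMEM59L (2.38 ± 0.63, from a dim 29.3 ± 20.1 to 125 ± 22.7). Only 1 of 6 other probe sets of RC3H2 and 0 of 1 of CHPF2 shared the direction. MANF passed adjusted over the list alone among 27 endoplasmic reticulum chaperone genes (limma adjusted p = 0.00742). With the replicate block, an alternative fixed at the start, limma called 0 (smallest adjusted p = 0.0795). With the batch as a block, chosen after the data were seen, limma called 3 probe sets at an adjusted p of 0.0482 each. They were MAP2K4 (lower) and the 2 brightest probe sets of DGCR8 and MIR1306 (higher). All 3 had the same sign in all 3 batches, which that fit favours, so this adds no support.

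The signal of the brightest DGCR8 and MIR1306 probe set was 1389 ± 138 with the empty vector, 1424 ± 86.9 with the tRNA vector and 2224 ± 234 with the hairpin vector (SD, n = 4). Its log2 fold change with the hairpin vector was 0.68 ± 0.10 (limma adjusted p = 0.336), and all 4 arrays lay above all 4 of the empty vector, with an exact permutation p of 0.0286, the smallest possible. For the next brightest the signals were 1066 ± 191 and 1580 ± 232 (0.57 ± 0.15, exact permutation p = 0.0571), and for the one after it 580.1 ± 100.3 and 859 ± 125 (0.57 ± 0.14, exact permutation p = 0.0286). The remaining, dim probe set stood at 1.15 ± 0.80. With the tRNA vector these 4 were at 0.039, 0.13, 0.016 and 0.37, from brightest to dimmest. The probe sets are assigned to neither gene, and they were chosen after their values were seen.

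**Figure D2:**
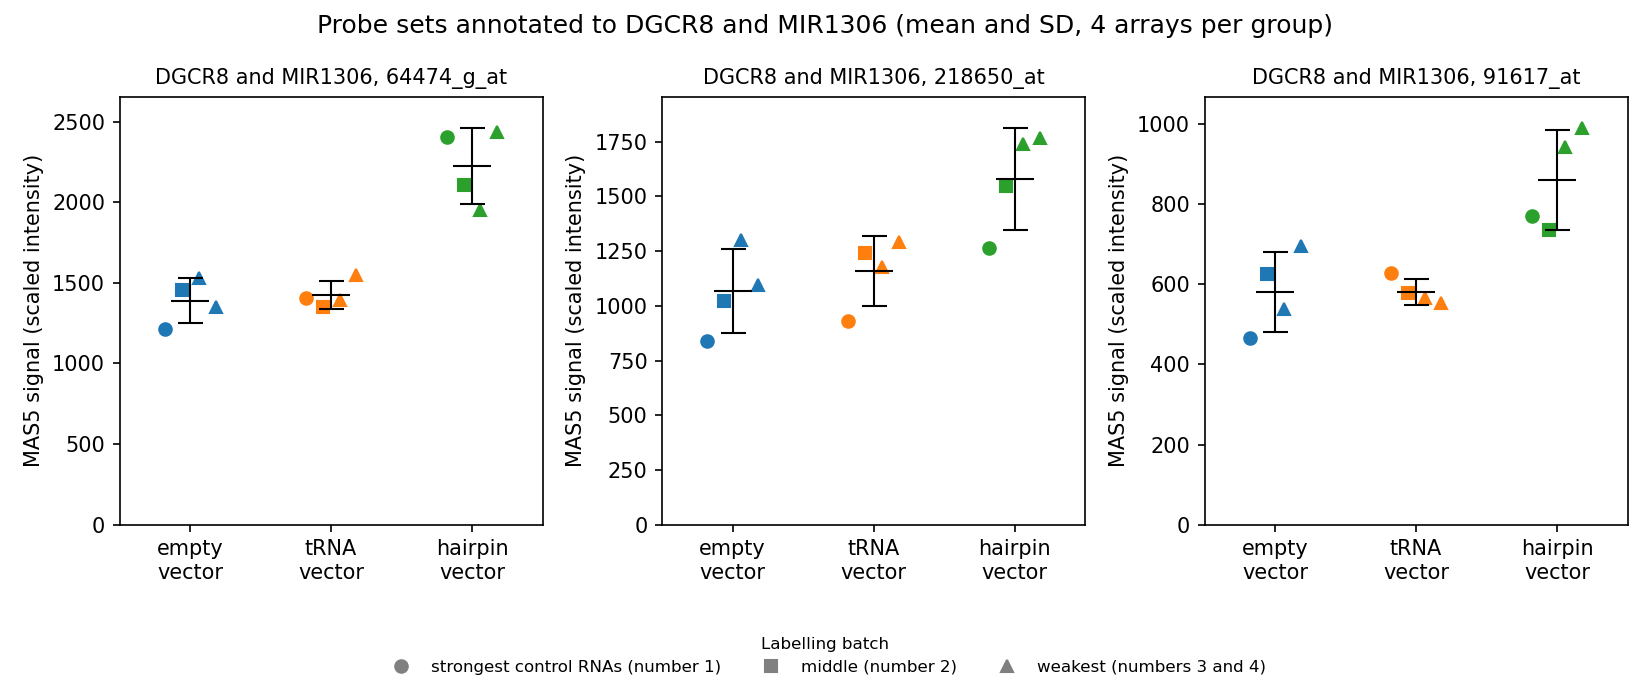
Signal (linear, vertical axis) on each array of the 3 brighter probe sets annotated to both DGCR8 and MIR1306, with the mean and SD of the 4 arrays per group and marker shapes for the 3 labelling batches. The hairpin vector means were 2224, 1580 and 859 against 1389, 1066 and 580.1 with the empty vector from left to right.

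DNA damage and replication genes gave no list call with the hairpin vector. Of 33 DNA damage signalling genes 24 were lower (mean -0.025, camera adjusted p = 0.634), with UIMC1, which brings BRCA1 to breaks, at -0.20 ± 0.10, and CDC25A, the phosphatase that drives S phase entry, at 0.24 ± 0.096, a direction that 0 of 2 other probe sets shared. Among p53 targets 18 of 27 were higher (mean 0.037, camera adjusted p = 0.894), and the members with the smallest p went opposite ways, TRIAP1 at -0.265 ± 0.072 and SESN2, a stress-induced inhibitor of mTORC1, at 0.26 ± 0.11. DNA replication genes split 23 higher and 23 lower (mean -0.0015, median 0.00015, camera adjusted p = 0.894), with ORC5 of the origin recognition complex at -0.25 ± 0.074 (1 of 2 other probe sets shared the direction) and RNASEH2A, of the nuclease that removes ribonucleotides from DNA, at -0.20 ± 0.086. Means were -0.012 for homologous recombination and Fanconi anaemia genes, 0.0060 for excision and mismatch repair, where the test pointed down, 0.051 for end joining, 0.0080 for E2F and G1/S genes, where the median was -0.0085, and 0.0020 for G2/M and mitosis genes, where the median was -0.011. The camera adjusted p of these 5 were 0.874, 0.894, 0.894, 0.894 and 0.894, and 0 of these genes passed adjusted over the list alone. Histone genes were higher in 13 of 17 (mean 0.23, exact permutation p = 0.0286, camera adjusted p = 0.359). MicroRNA machinery (0.021, median -0.0084), tRNA transcription and processing (-0.0066, median 0.0021), ribosomal proteins (-0.029) and oxidative phosphorylation (0.0053, where the test pointed down) did not pass (camera adjusted p = 0.894, 0.894, 0.434 and 0.894). For ribosomal proteins the sign depended on the arrays kept, with batch values of -0.33, 0.16 and 0.026. With the preset correlation that list passed in 4 of 23 other settings. It was lower without empty vector array 4 or hairpin vector array 2 (medians of -0.065 and -0.11) and higher without hairpin vector array 1 or the strongest batch (0.057 and 0.076). With its estimated correlation of 0.70, the planned fit gave a camera adjusted p of 0.922.

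Between the vectors, 21 of 27 measured p53 target genes had a higher mean with the hairpin vector than with the tRNA vector, with a list mean of 0.15 on the log2 scale. The list passed camera with the preset correlation (adjusted p = 4.2e-06) and not with an estimated correlation (adjusted p = 0.130). Its exact permutation p was 0.0286, the smallest possible. TP53I3 stood at 0.47 ± 0.12, SESN2 at 0.41 ± 0.11, ZMAT3 at 0.36 ± 0.12 and AEN at 0.24 ± 0.082. Transcripts of ribosomal proteins were lower in 46 of 48 and those of oxidative phosphorylation in 35 of 47, with means of -0.12 and -0.064. Both passed camera with the preset and not with an estimated correlation (adjusted p = 0.782 for both). The comparison asks whether the sources of CU1276 differ from each other.

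The p53 target mean was higher in 4 of 4 same-number comparisons, and by 0.15, 0.16 and 0.14 in the 3 batches, which are the same arrays. The list did not pass fry (adjusted p = 0.0994). Its camera adjusted p with the batch as a block and an estimated correlation was 0.0189, and its fry adjusted p with that block was 0.00148. Adjusted over the list alone, 3 of its genes passed in limma (TP53I3, SESN2 and, in the other direction, TRIAP1 at -0.27 ± 0.072, adjusted p = 0.0195), against 0 over all genes. For ribosomal proteins the camera adjusted p was 3.52e-10, with adjusted p = 0.782 with an estimated correlation and an exact permutation p of 0.4, and batch values were -0.16, -0.15 and -0.093. The call ended with quantile normalization (camera adjusted p = 0.920) and without hairpin vector array 1 (0.0559). The ribosomal median, -0.13, was -0.0031 with quantile normalization and ran from -0.215 (without hairpin vector array 2) to -0.047 (without tRNA vector array 2) when single arrays were left out. For oxidative phosphorylation the adjusted p was 2.05e-04, or 0.782 with an estimated correlation, with batch values of -0.036, -0.067 and -0.077, and that call too ended with quantile normalization (camera adjusted p = 0.7755). Over all settings the median of that list, -0.061, ran from -0.086 to -0.0093. The members with the smallest p were RPL36 (-0.21 ± 0.067), RPL23A (-0.22 ± 0.094), RPL22 (-0.17 ± 0.085), RPL18 (-0.16 ± 0.083, a direction that 0 of 2 other probe sets shared), NDUFB10 (-0.34 ± 0.11, 0 of 1) and NDUFV1 (-0.295 ± 0.12) of complex I, UQCRC1 (-0.20 ± 0.075) and ATP5F1A, of ATP synthase (-0.15 ± 0.064).

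**Figure D3:**
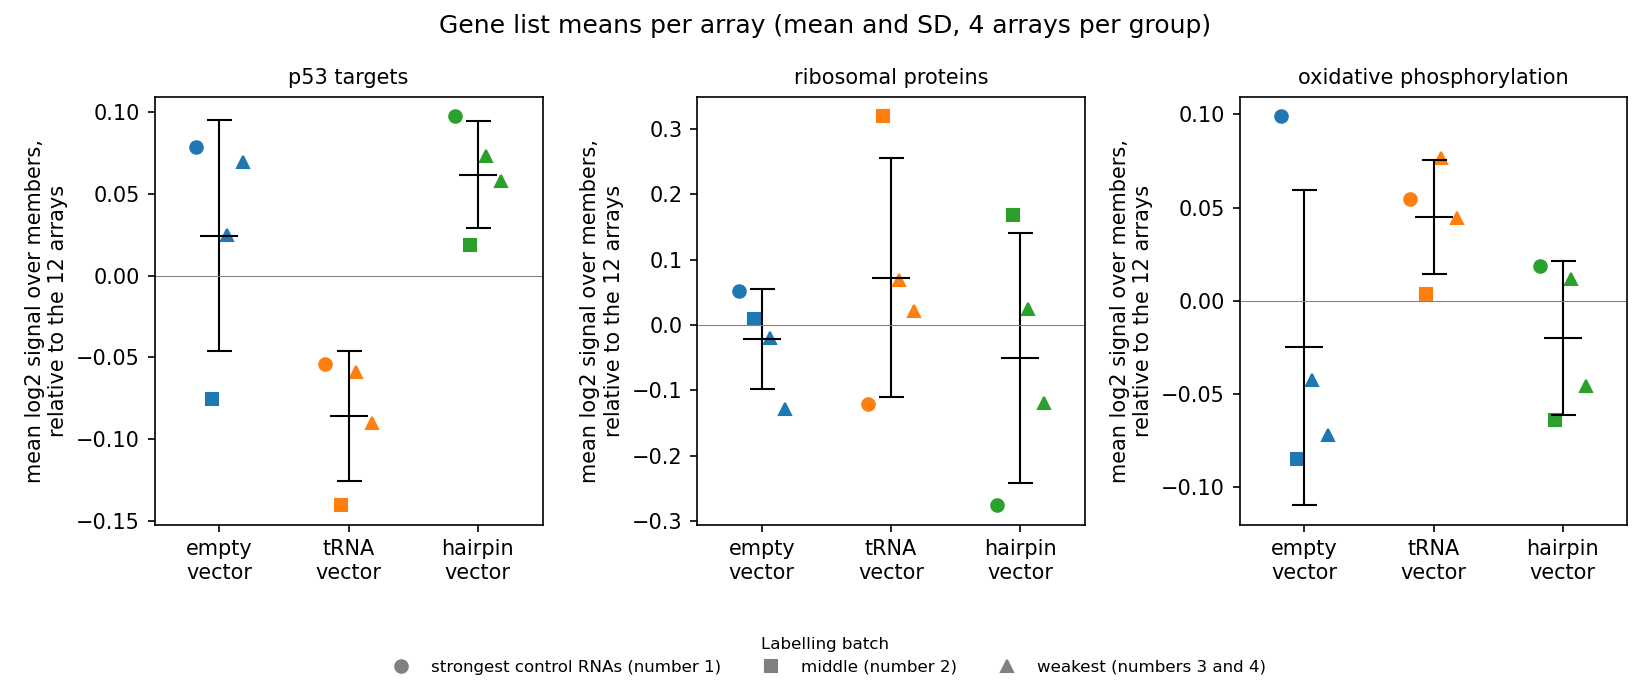
Mean log2 signal of the measured genes of 3 lists (p53 targets, ribosomal proteins and oxidative phosphorylation) on each array, each gene centred on its mean over the 12 arrays (vertical axis), with the mean and SD of the 4 arrays per group and marker shapes for the 3 labelling batches. The p53 target mean was lower in the tRNA vector group than in the others, at -0.11 against the empty vector, with the hairpin vector 0.15 above the tRNA vector, while for ribosomal proteins the SD within the tRNA vector group was 0.18.

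Over all probe sets limma gave 0 changed between the vectors after adjustment (smallest adjusted p = 0.236), with 1271 at an unadjusted p under 0.05 (754 higher, 517 lower) where chance gives 1638, and the plain two-sample test gave 0. The unadjusted count was 2601 (1380 higher, 1221 lower) with the batch as a block, against the same 1638. Probe sets are not independent and no range around that number was computed, so no excess over chance is claimed. Values only, the lowest by moderated t were MANF (-0.42 ± 0.067), MAP2K4 (-0.50 ± 0.086), SPINT2, a protease inhibitor (-0.48 ± 0.10), ASPDH (-1.93 ± 0.47, from 147 ± 42.1 to a dim 38.2 ± 9.08) and AARS1 (-0.27 ± 0.066). The highest by moderated t were CIRBP (0.43 ± 0.081), DCTN4 (0.38 ± 0.078), VEGFA, the angiogenic growth factor (0.43 ± 0.095), C8orf33 (0.36 ± 0.082) and HSPBP1, an HSP70 cochaperone (0.66 ± 0.15). Other probe sets shared the direction in 2 of 4 cases for CIRBP, 0 of 2 for DCTN4, 1 of 3 for VEGFA and 0 of 1 for C8orf33. With the batch as a block limma called 8 probe sets, 6 higher and 2 lower, at adjusted p of 0.00120 to 0.0315. All 8 had the same sign in all 3 batches, which such a fit favours, so this adds no support. They were CIRBP, PPP2R5C, a phosphatase subunit (0.52), IFNGR1, the interferon gamma receptor (0.40), SEC61A2, of the translocon (0.67), the brightest DGCR8 and MIR1306 probe set (0.64), the probe set not listed with a gene that was lower with the tRNA vector (0.85), MANF and MAP2K4, of which PPP2R5C, IFNGR1 and SEC61A2 were chosen after their values were seen. The other DGCR8 and MIR1306 probe sets stood at 0.44 ± 0.15, 0.555 ± 0.14 and, for the dim one, 0.79 ± 0.80.

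Of 33 DNA damage signalling genes 14 were higher with the hairpin vector than with the tRNA vector (mean -0.0061, camera adjusted p = 0.982), ATM at 0.43 ± 0.14 (2 of 4 other probe sets shared the direction) and CDC25A at 0.21 ± 0.096 (0 of 2). Of 46 DNA replication genes 31 were lower (mean -0.037, camera adjusted p = 0.131), with GMNN, which blocks relicensing of origins, at -0.30 ± 0.11 and RNASEH2A at -0.23 ± 0.086. The replication mean was lower in 4 of 4 same-number comparisons, with an exact permutation p of 0.4. That list passed fry with the batch as a block (fry adjusted p = 0.0343) and not in the planned fit (0.699), nor camera with that block (adjusted p = 0.0590, or 0.271 with an estimated correlation). Means were 0.016 for homologous recombination and Fanconi anaemia genes, where the median was -0.018, 0.0042 for excision and mismatch repair, where the test pointed down, 0.059 for end joining, 0.043 for E2F and G1/S genes and 0.011 for G2/M and mitosis genes. The camera adjusted p of these 5 were 0.982, 0.982, 0.982, 0.399 and 0.982. MicroRNA machinery (0.040, median -0.0026), tRNA transcription and processing (-0.034), aminoacyl-tRNA synthetases (-0.056) and histone genes (0.18) did not pass (camera adjusted p = 0.770, 0.242, 0.0551 and 0.389). The synthetase list passed with the batch as a block (camera adjusted p = 0.0424, or 0.722 with an estimated correlation), which made 4 lists in place of 3. It passed in 5 of 23 other settings in all, and with an estimated correlation its adjusted p was 0.782. Adjusted over the list alone, 1 gene passed in limma in each of end joining, histone genes, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones and glycolysis and hypoxia, and 2 in the integrated stress response, against 0 over all genes.

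The vectors were also compared for shared changes against the empty vector. limma gave 0 probe sets changed the same way by both after adjustment, and 186 at an unadjusted p under 0.05, and the plain two-sample test gave 0 changed for either vector. Simulated groups without change that share the empty vector arrays gave 164.9 on average (138 to 198), and independent lists would give 16.3. Log2 fold changes of the vectors correlated at r = 0.488 across probe sets, which are not independent replicates, against 0.4997 in simulations without change (0.483 to 0.519). The covariance was 0.0603 against 0.0648. With 2 different empty vector arrays given to each vector, the 6 ways gave r = -0.106 to -0.0164. None of these ways balances the labelling batches, so their r does not show what the shared arrays add. The simulation above takes its spread from the fit without the batch. In the fit with the batch as a block, 423 probe sets went the same way at an unadjusted p under 0.05, against 174.1 in simulations of that fit (141 to 206) and 69.2 for independent lists. The covariance was 0.0603 against 0.0520 there (0.0494 to 0.0543), while r was 0.488 against 0.5007 (0.484 to 0.518). That simulation was added after the data were seen. The count and the covariance thus lay above their simulated ranges, r lay within its range, and 0 probe sets passed the same way after adjustment in that fit. Since probe sets are not independent replicates, no shared effect is claimed from the excess, and none is excluded.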

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

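The tests of the labelling batch and of RNA integrity on the p53 targets, of cross-hybridisation and the labelling batch on the DGCR8 and MIR1306 probe sets, and of array-to-array drift and the labelling batch on the ribosomal proteins were chosen only after the results were seen, as was the fit with the batch as a block.

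The effects of the vectors against the empty vector differed from each other, by camera on the hairpin vector minus the tRNA vector, for 3 lists, with mean log2 differences of 0.1475 for p53 targets, -0.0645 for oxidative phosphorylation and -0.123 for ribosomal proteins. Each of these was lost with an estimated correlation (camera adjusted p = 0.130, 0.782 and 0.782).

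The p53 target list was lower with the tRNA vector than in both other groups. Batches hold the groups equally, so an added difference between labelling batches cancels. A shift carried by a single batch is argued against, since the sign was the same in all 3 batches against both groups. That argument is limited. Arrays numbered 1 and 2 each form a batch with 1 array per group, and both comparisons use the same tRNA vector arrays. The larger camera adjusted p with the batch as a block and an estimated correlation was 0.0321. RNA integrity as read from GAPDH is argued against. Group means of its 3' to 5' ratio differed by at most 0.0203 against an SD of 0.165. The correlation of that ratio with the list mean over 12 arrays did not pass (r = 0.214, permutation p = 0.509, and rho = 0.294, permutation p = 0.357). Adjusted over these 2 relations the permutation p was 0.509. The r was 0.0550 without the 2 arrays farthest from the median and -0.166 within the 6 arrays of the weakest batch. The same ratio for ACTB varied more, at 2.48 ± 0.592 with the empty vector, 2.29 ± 0.362 with the tRNA vector and 2.38 ± 0.515 with the hairpin vector (SD, n = 4). Its exact permutation p was 0.657 to 0.771, and its relation to the list mean was not tested. A drift of genes of the same brightness is argued against by 10000 random lists matched on signal. Their central 95% of medians ran from -0.045 to 0.064 while the list stood at -0.10, percentile 0.01. Between the vectors that range was -0.059 to 0.049 against 0.14. The list had been picked by camera on the same fold changes, and random lists do not carry the correlation among its genes. The percentile is therefore no measure of chance. What stays open is chance, given the estimated correlation and fry (adjusted p = 0.129 and 0.0994) in the planned fit and the split counts below, and a lower p53 output with the tRNA vector may be a hypothesis for other cells, since it was found and tested on the same data and 293T cells carry viral proteins that act on p53.

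The probe sets annotated to DGCR8 and MIR1306 were higher with the hairpin vector. A single cross-hybridising probe set is argued against, since 4 of the 4 were higher by 0.5 or more on the log2 scale against the empty vector. Against the tRNA vector 3 of the 4 were. That count depends on the dim one (0.79 ± 0.80), since 1 of the brighter ones stood at 0.44 ± 0.15. Batches hold the groups equally, so an added batch difference cancels. A rise carried by a single batch is argued against, as the 3 brighter ones were higher in 24 of 24 same-number comparisons. These are not 24 separate observations, since they count the same 4 hairpin vector arrays for each probe set and against both other groups. The probe sets were also chosen after their values were seen. DGCR8 transcripts are known to be cut by the complex that cuts primary microRNAs, so less of that cutting might raise them. To look at this, 23 genes were picked by symbol, those named for a microRNA or its host transcript, with DLEU2 among them. Their median was 0.023 on the log2 scale (percentile 61.2 of matched random lists, which ran from -0.13 to 0.15). That keeps less cutting open, because most of them are dim and a symbol does not show that a probe set reads a primary microRNA transcript. A transcript that the hairpin vector itself adds to these probe sets was not tested.

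Ribosomal protein transcripts were higher with the tRNA vector and lower with the hairpin vector relative to it. After quantile normalization the list median kept 7.14% of its size against the empty vector and 2.31% between the vectors. A drift of the brightest transcripts could account for it. But that step gives all arrays the same distribution, so it would also shrink a real shift shared by the brightest transcripts. It cannot tell these apart. A drift from array to array that its genes share stays open. The exact permutation p of the list mean was 0.371 and 0.4, but that test ignores the array numbers. Between the vectors the list was lower in 4 of 4 same-number comparisons (-0.155, -0.151, -0.0455 and -0.141, SD 0.0521), where the exact sign-flip p of 0.125 is the smallest possible, so 4 numbers are too few to decide. Against the empty vector these differences were -0.172, 0.311, 0.0886 and 0.1495 (SD 0.2004, exact sign-flip p = 0.5). The sign held in 5 of 6 within-batch values, so the pattern is not even across batches, although batches hold the groups equally and an added batch difference cancels. No biological explanation was tested.

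In groups of 4 arrays 1 array can lie far from the others, with a gap to its neighbour, as a share of the range, above Dixon's 95% critical value for 4 values. This held for 9 of 216 groups looked at, where chance gives 10.8. These were RPA3 with the empty vector (0.853, array 1 higher), RPS21 with the hairpin vector (0.850, array 1 lower), CHPF2 with the hairpin vector (0.888, array 4 lower), PFAS with the empty vector (0.916, array 1 higher), RNASEH2A with the tRNA vector (0.899, array 1 higher), SPINT2 with the empty vector (0.927, array 4 higher), NDUFB10 with the hairpin vector (0.846, array 3 higher), and IFNGR1 with the tRNA vector (0.909, array 1 higher) and with the hairpin vector (0.901, array 1 higher).

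The 8 arrays of a comparison can be split into groups of 4 in 35 ways. With 0 changed probe sets in each real split, all 35 give as many, and the highest other split gave 96, 30 and 0 in the tRNA vector, hairpin vector and between-vector comparisons. The 96 and the 30 came from the split of arrays numbered 1 and 2 against 3 and 4. That split keeps each labelling batch whole, puts the 2 with stronger control RNAs together, and points to a structure of the samples. Since the batches follow the replicate numbers, labelling cannot be told apart here from other differences between replicates. With the batch as a block the real counts were 4, 3 and 8. For those counts 12 splits keep the batches balanced, too few for a share under 0.05, with 1, 2 and 1 splits as large and 1, 5 and 0 in the highest other. For gene lists, 6, 26 and 9 of the 35 splits gave as many as the real 3, 1 and 3, with 6, 4 and 7 in the highest other. Many of these splits break the batches. Among those that keep the batches balanced the highest other gave 6, 4 and 3, so chance cannot be excluded for these counts.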

How the results depend on the processing

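The fits with the batch as a block and without the strongest spike-in batch were chosen after the data were seen. Changed probe sets stayed at 0 in each comparison with limma under the alternatives fixed at the start except, for the hairpin vector against the tRNA vector, 1 with array weights and 6 with the replicate block. With the batch as a block they were 4, 3 and 8 (tRNA vector, hairpin vector and between-vector comparisons), since the block removes spread, and without the strongest spike-in batch 1 in the last. Changed gene lists, 3, 1 and 3 in the results, were 0, 0 and 0 with the estimated inter-gene correlation and 1, 0 and 1 with quantile normalization. For the hairpin vector against the empty vector they were also 0 with the mean of all probe sets of a gene, no filter, no trend, array weights and only the 2 groups, and 0 to 2 without single arrays. The p53 list passed in 23 of 23 settings with the preset correlation in both comparisons (highest camera adjusted p 0.00239 and 6.06e-04), with medians of -0.16 to -0.079 and 0.11 to 0.18.

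The RPA1 log2 fold change ran from -0.249 to -0.174 with the tRNA vector and from -0.283 to -0.18 with the hairpin vector without single arrays, and between the vectors from -0.0698 to 0.0328, with 0.017 after quantile normalization. RPA2 ran from -0.0588 to 0.051, -0.0679 to 0.042 and -0.0382 to 0.019 in these comparisons, and RPA3 from -0.0693 to 0.0609, -0.112 to 0.0352 and -0.0854 to 0.009. After quantile normalization RPA2 and RPA3 stood at 0.0268 and 0.0412 between the vectors, and RPA3 at 0.038 for the tRNA vector without the strongest spike-in batch. The correlation of the vectors' fold changes ran from 0.432 to 0.580 without single arrays. The cause of these changes was not tested. Of 1836 values of named genes other than RPA1 under alternatives, 1811 kept direction and side of the threshold, 10 newly passed and 15 turned sign, in RPA2 and RPA3; for RPA1, 4 values turned sign, all between the vectors. A test of sites complementary to the small RNA in untranslated regions was not run. Dim signals near background limit DTX2, TMEM59L, ASPDH and 1 of the DGCR8 and MIR1306 probe sets.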

Other observations

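In the planned fit none of the lists here passed its threshold. With the batch as a block, which was chosen after the data were seen, the list of TGF-beta, matrix and adhesion genes passed fry with the tRNA vector (fry adjusted p = 0.0313) and not camera (adjusted p = 0.636).

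Markers of other cell types were few among tested genes. 13 B-cell markers had mean log2 differences of -0.17 with the tRNA vector, -0.099 with the hairpin vector and 0.071 between the vectors, and 9 T-cell and myeloid markers of -0.38, -0.41 and -0.034. Fibroblast markers (13) stood at -0.11, 0.0996 and 0.21, epithelial markers (8) at 0.069, -0.035 and -0.10, and erythroid markers (3) at 0.25, 0.23 and -0.018, in the same order. The camera adjusted p of these lists were 0.301 to 0.982.

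Stress and signalling genes followed no common direction. In the order of the 3 comparisons, means were -0.015, 0.017 and 0.032 for 28 integrated stress response genes, 0.026, 0.015 and -0.012 for 27 endoplasmic reticulum chaperones, and -0.075, -0.070 and 0.0048 for 19 heat shock proteins, of which 16 were lower with the hairpin vector (camera adjusted p = 0.301). They were -0.038, -0.045 and -0.0062 for 31 interferon-stimulated genes, 0.046, 0.0059 and -0.040 for 16 NF-kB and inflammatory genes, 0.024, 0.040 and 0.015 for 33 immediate early genes, 0.015, 0.021 and 0.0053 for 27 apoptosis regulators, -0.019, -0.12 and -0.099 for 24 metallothionein and oxidative stress genes, and 0.086, 0.12 and 0.037 for 30 genes of TGF-beta, matrix and adhesion. In metabolism and gene expression they were -0.0696, 0.029 and 0.099 for 16 genes of serine, glycine and one-carbon metabolism, 0.031, 0.012 and -0.019 for 25 of sterol and fatty acid synthesis, -0.0089, 0.017 and 0.026 for 32 of glycolysis and hypoxia, -0.029, -0.010 and 0.019 for 30 of ribosome biogenesis, and 0.023, 0.010 and -0.013 for 37 splicing factors. The camera adjusted p of these lists were 0.301 to 0.982, and 0 of their genes passed adjusted over the list alone other than those counted in the results. The median or the test differed in sign from the mean, so that no direction is given, with the tRNA vector for the lists of one-carbon metabolism, interferon-stimulated genes, NF-kB, glycolysis, apoptosis and metallothioneins, and with the hairpin vector for the integrated stress response, interferon-stimulated genes, NF-kB, immediate early genes, sterol synthesis, splicing, apoptosis and fibroblast markers. Between the vectors this was so for one-carbon metabolism, the integrated stress response, heat shock proteins, interferon-stimulated genes, NF-kB, immediate early genes, glycolysis, ribosome biogenesis, apoptosis and TGF-beta.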
